A study of Homo sapiens with 8 samples.

How the data were processed

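MicroRNAs were profiled in 8 samples of a melanoma cell line model, 4 of the parental line A375P and 1 of each variant line MA1, MC1, MA2 and MC2. Per the labels' protocols, total RNA with an integrity number of 6 or more was used, 200 ng of it was labelled with Cy3, and it was hybridized for 22 hours to Agilent human miRNA arrays. Spot intensity was extracted from the scans with Agilent Feature Extraction, version 9.5.3.1 for 5 arrays and 10.5.1.1 for 3 arrays, per the file headers. The main values were the background-subtracted processed signals of that software, deposited as intensity on a linear scale. The deposited table of log2 values correlated with log2 of the software's total signal per miRNA at 0.998 or more on each array, so its scale is log2. The median of its values was 6.65 on parental replicate 1, 7.19, 7.19 and 7.07 on parental replicates 2 to 4, and 6.51 to 6.68 on the variants. Its normalization and centring are not given in the sources used here, and it was used only as an alternative. It lacks values for undetected miRNAs, so only miRNAs with a value on every array were tested there, fewer than with the main values.

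Each array held 12784 spots that were not controls, for 2421 probes of 723 human and 76 viral targets. Spots flagged as outliers, 731 to 1019 per array, were left out, and 0 spots were saturated. Spots of a probe were averaged. Each array was scaled to the 75th percentile of the 289 probes well above background on all 8 arrays, which was 413 to 452 on the second slide and 612 to 854 on the first. The probes of a miRNA were summed, a floor of 4.75 on the log2 scale was set, and log2 was taken. In 1 of 70 called miRNAs with at least 2 usable probes, a probe changed in the opposite direction. The 236 human miRNAs well above background on at least 2 arrays were tested. For depth, 19.1% to 27.1% of spots were well above background on an array. For a miRNA not well above background on any array of a group, a lower bound of the fold is given: the mean of the brighter group over all its arrays against the mean, per array, of the higher of the floored value and the lowest value detected.

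Groups were taken from the labels. Differences were fitted with limma 3.58.1 in R 4.3.3 and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Variants and parental samples were compared in 2 groups. Rounds were compared in 3 groups that share 1 estimate of the spread, and MC and MA lines in a fit with round as a term. miR-146a was also tested by an exact two-sided permutation test. Lists of miRNAs fixed before the data were examined were tested with camera, at a preset correlation of 0.01 and with an estimated correlation. The named miRNAs were miR-146a, the 10 largest called changes per direction whose 4 variant values lay outside the parental range, the 5 largest per direction in the other comparisons, up to 4 members of each list by p, and those detected on every array of 1 group and on 0 of the other.

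Slide and scan were read from the file headers and coincided with the software version. They were fitted as a block, since the first slide held parental and variant arrays. It held 1 parental array, so with the block each difference from the parental line equals the variants minus parental replicate 1. The spread then comes from the variants and from parental replicates 2 to 4, which differed little among themselves. Passing with the block therefore does not account for variation between parental samples on the first slide. Alternatives in signal, scaling, probe rule, filter, floor and model, and leaving out each array, were also run. limma set very small variances of miRNAs at the floor away from zero. Data were simulated with the parental means and limma's moderated spread per miRNA, the same for all arrays and independent between them. There the test of variants against parental samples recovered 74.5% of 1.5-fold, 91.0% of 2-fold and 98.5% of 3-fold changes over 236 miRNAs, without a slide effect or floor. The real median SD was 0.042 in parental replicates 2 to 4 and 0.248 in the variants, so these shares need not hold for the real arrays. Names are those of the array design. Of the 723 human miRNAs, 713 matched a miRNA gene in the RefSeq table of GRCh38, used for names alone, and 10 did not, miR-923 and miR-801 among them. Positions are of the probed stretch in build hg18 as the files give them.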

Results

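MicroRNA levels were measured on 1-colour Agilent arrays in a human melanoma model. A375P is a melanoma cell line that carries an activated B-RAF kinase and metastasizes poorly. MA1 and MC1 are variant lines recovered after 1 round of injection of A375P into mice, and MA2 and MC2 after 2 rounds. The 8 arrays held 4 parental samples and 1 sample of each variant line. The labels call the parental samples biological replicates and do not say how their cultures were kept apart, so p-values measure only the spread between these samples. Of 723 human miRNAs on the array, 202 were detected on parental replicate 1, 162 to 172 on parental replicates 2 to 4, and 187 to 235 on the variant arrays. The number of arrays limits the precision. Parental replicate 1 and the 4 variant arrays shared a slide, and parental replicates 2 to 4 were on a second slide.

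The study is named for miR-146a, a regulator of NF-kappaB signalling, and the first comparison asked whether its level differed between the variants and the parental line. miR-146a was higher in all 4 variants, with a geometric mean signal of 2047 (log2 SD 0.45, n = 4) against 934 (log2 SD 0.10, n = 4). The difference was 1.13 on the log2 scale, or 2.19-fold, with a standard error of 0.22 (limma, adjusted p = 0.0059). The exact two-sided permutation test over 70 assignments gave p = 0.0286, the smallest it can give. That test takes the 8 arrays as exchangeable, which the 3 similar parental arrays of the second slide are not. The descent of the variant lines from each other is not given either, so this p may be too small. MA1 and MA2 lay 2.67-fold above the parental mean, MC2 2.34-fold and MC1 1.38-fold. The probes cover positions 159844960 to 159844978 of chromosome 5 in build hg18, per the file headers. Within the first slide the variants were 1.27 log2 units above the single parental array there. With the slide as a block limma's adjusted p was 0.07, and with scaling over all probes the difference was 0.65 at an adjusted p of 0.10.

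**Figure D1:**
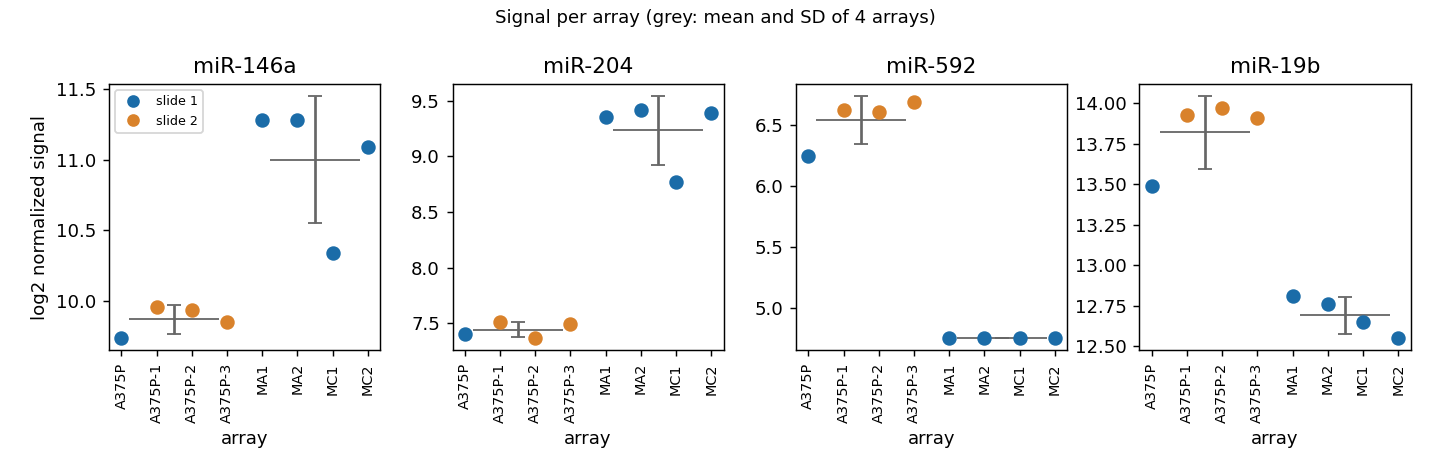
Log2 normalized signal of miR-146a, miR-204, miR-592 and miR-19b on each of the 8 arrays, coloured by slide, with the mean and SD of 4 parental and 4 variant arrays in grey. miR-146a averages 9.87 in parental samples and lies 1.13 higher in the variants.

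The comparison of all 4 variants with the parental line asked which miRNAs accompany metastatic ability. miR-204, which is abundant in pigment cells, rose by 1.79 log2 units (SE 0.15) from 7.44 ± 0.07 to 9.23 ± 0.31 (SD, n = 4 each; adjusted p = 0.00065). miR-592 was well above background on all 4 parental arrays and on 0 variant arrays, and was at least 3.46-fold lower in the variants (adjusted p = 7.5e-05). Members of the miR-17-92 cluster, which promotes proliferation, fell, with miR-20a changing by -1.18 (SE 0.14), miR-19b by -1.13 (SE 0.12) and miR-19a by -1.07 (SE 0.14). In total 94 of 236 tested miRNAs passed an adjusted p of 0.05 in limma, 52 higher and 42 lower in the variants.

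Ranked here are called miRNAs whose 4 variant values all lay outside the range of the 4 parental values. The other miRNAs with the largest rises were miR-874, by 2.52 log2 units (SE 0.48), miR-513b, by 1.73 (SE 0.41), and miR-371-5p, by 1.67 (SE 0.37). Next were miR-494, by 1.60 (SE 0.40), and miR-923, by 1.59 (SE 0.32), a name with no miRNA gene in the RefSeq table. Behind them, under the same rule, came miR-218, by 1.39 (SE 0.22), and miR-940, by 1.37 (SE 0.33). miR-135a* and miR-363 were not well above background on any parental array and were at least 2.68-fold and 2.46-fold higher in the variants, where 3 of 4 arrays measured each. miR-874, miR-371-5p and miR-513b were measured on 1 of 4 parental arrays. The differences of miR-494, miR-513b, miR-371-5p and miR-874 were 0.58, 0.85, 1.02 and 1.45 with the slide as a block. Of the 10 largest rises, 2 passed in that fit, miR-204 and miR-218. The other miRNAs with the largest falls were miR-221*, which changed by -1.48 (SE 0.22), miR-7-1* by -1.22 (SE 0.17), miR-130a by -1.14 (SE 0.21), miR-7 by -1.10 (SE 0.23), miR-361-3p by -1.03 (SE 0.15) and miR-20a*, the opposite strand of miR-20a in the cluster, by -1.001 (SE 0.11). In the fit with the slide block, 5 of the 10 largest falls passed (miR-592, miR-20a, miR-19b, miR-19a and miR-20a*). miR-503, miR-629, miR-873 and miR-876-5p were well above background on every variant array and on 0 parental arrays. They were at least 2.00-fold, 1.91-fold, 2.30-fold and 1.87-fold higher in the variants, and none of them passed with the slide as a block (adjusted p = 0.066, 0.086, 0.091 and 0.11). miR-424* was detected in the same way, at a difference of 0.11 that did not pass the test (adjusted p = 0.45). With normexp background correction, which also shifted the median of all tested miRNAs by -0.30, miR-503, miR-629, miR-873, miR-876-5p, miR-135a*, miR-363 and miR-513b had differences of -0.36 to -0.020.

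**Figure D2:**
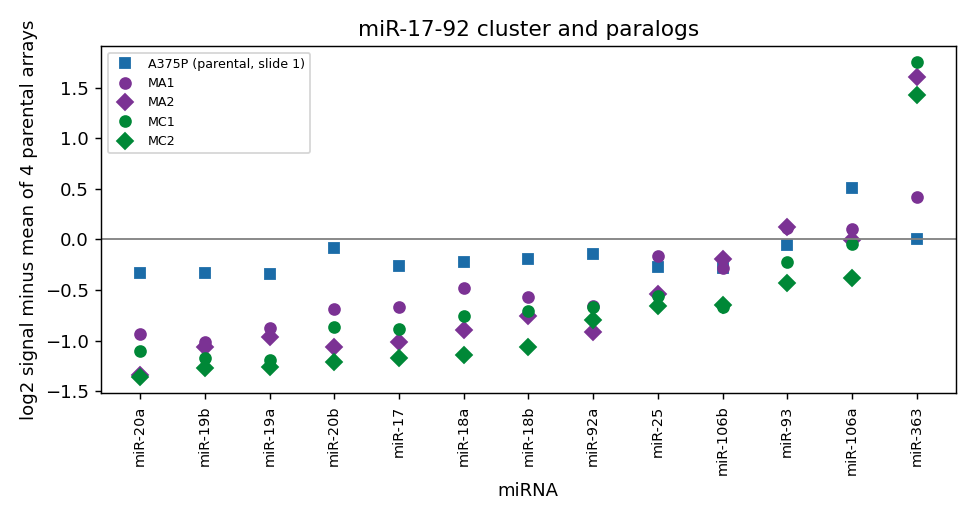
Log2 signal of the 13 tested members of the miR-17-92 list minus the mean of 4 parental arrays, for the parental array of the first slide and for each variant line. In 9 members all 4 variants lie below that parental array, and in miR-363 the difference is 1.30.

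Of 13 tested members of the miR-17-92 cluster and its paralogs, 10 fell, 1 rose and 2 did not pass the test, and the same counts resulted when adjusted over the list alone. The member that rose was miR-363. The median member differed by -0.77, and camera placed the list lower than other miRNAs at an adjusted p of 6.7e-05 with the preset correlation. With the estimated correlation of 0.43 the camera adjusted p = 0.73. With the slide as a block the median was -0.60, at a camera adjusted p of 0.00015 with the preset correlation. The estimated correlation was not run with the block. In the block fit 5 of the 11 called members passed in limma, miR-19a, miR-19b, miR-20a, miR-20b and miR-92a. miR-92a changed by -0.76 (SE 0.08) and miR-20b by -0.95 (SE 0.12).

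Of the 13 tested miRNAs reported as pro-metastatic or oncogenic in melanoma, 4 rose, 1 fell and 8 did not pass, as they did when adjusted over the list alone, and camera gave an adjusted p of 0.51. miR-199b-5p rose by 0.57 (SE 0.16) and miR-532-5p by 0.50 (SE 0.15), the latter turning to -0.14 with normexp, while miR-30b changed by -0.31 (SE 0.06), with 1 of its probes changing the other way. Of 15 tested miRNAs reported as tumour-suppressive in melanoma, 4 rose, 1 fell and 10 did not pass, again as when adjusted over the list alone (camera adjusted p = 0.56). miR-148b rose by 0.56 (SE 0.07) and miR-29c by 0.47 (SE 0.08), and the value of miR-29c was -0.013 with scaling over all probes. miR-18b changed by -0.77 (SE 0.12). The slide block left 1 of 5 calls in the pro-metastatic list, miR-532-5p, and 2 of 5 in the tumour-suppressive list, miR-148b and miR-204. Of 8 melanocyte lineage markers on the array, 2 were detected on any array, miR-204 and miR-146a. The others, miR-211 among them, were not detected. Both detected markers rose and passed when adjusted over the list alone, but of the pair miR-204 alone passed with the slide block.

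Among the other families, 3 of 5 members of the miR-23/27/24 clusters fell, with miR-23b changing by -0.90 (SE 0.19), miR-27b by -0.56 (SE 0.12) and miR-24 by -0.37 (SE 0.08), and the camera adjusted p was 0.28. None of these 3 passed in the fit with the slide block, where miR-23b was -0.80, miR-27b -0.59 and miR-24 -0.14 (adjusted p = 0.14, 0.097 and 0.14). The value of miR-24 turned to 0.15 with quantile normalization. In the family of miR-15, miR-16 and miR-195, miR-424 rose by 0.91 (SE 0.09), miR-16 changed by -0.60 (SE 0.16) and miR-15b by -0.59 (SE 0.17), and 3 of 6 did not pass. In the fit with the slide block miR-16 was -0.28 and miR-15b -0.15, and neither passed (adjusted p = 0.48 and 0.62). These counts for both families were unchanged when adjusted over the list alone. In the let-7/miR-98 family 1 of 9 members, let-7i, rose by 0.56 (SE 0.15), and 0 passed when adjusted over the list alone. Of the markers of other cell types, 0 epithelial, 0 endothelial and 0 muscle miRNAs were tested, because fewer than 2 arrays detected them. Of 5 mesenchymal or fibroblast markers 2 rose, miR-199b-5p and miR-10b, the latter by 0.61 (SE 0.19), and 3 rose when adjusted over the list alone. Of the liver markers miR-194 rose by 0.85 (SE 0.16), turning to -0.20 with normexp, and miR-192 differed by 0.09 (adjusted p = 0.78). In the fit with that block let-7i passed, and miR-199b-5p, miR-10b and miR-194 did not.

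The variants lay outside the range of the 4 parental values for 86 of the 236 miRNAs, or 36.4%, where chance gives 2.86% for 8 independent arrays. Parental replicates 2 to 4 shared a slide and had a median SD of 0.042, so that share is too low for these arrays. With the slide as a block 29 miRNAs passed, 14 higher and 15 lower, and 1 passed within the first slide, which held 1 parental array. All 94 kept their direction with the block, and 25 of the 94 passed in it. The block difference is measured from parental replicate 1, which is also part of the parental mean that chose the 94. A kept direction is therefore little support. In 80 of the 94 all 4 variants lay on 1 side of parental replicate 1. A fit with parental replicates 2 to 4 averaged into 1 sample called 9 miRNAs in limma, and 72 at an unadjusted p under 0.05. Scaling over all probes moved the split of higher against lower calls to 16 and 58, and shifted the median of all tested miRNAs by -0.38. The split was 36 and 47 with quantile normalization. With the deposited log2 values it was 39 and 53, and the median shifted by -0.12. Those values cover fewer miRNAs, since any with a missing value was left out. The main values of miRNAs detected on all arrays gave 31 and 36, with a shift of -0.084, so scaling is not separated from that selection. With normexp background correction the split was 14 and 72.

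**Figure D3:**
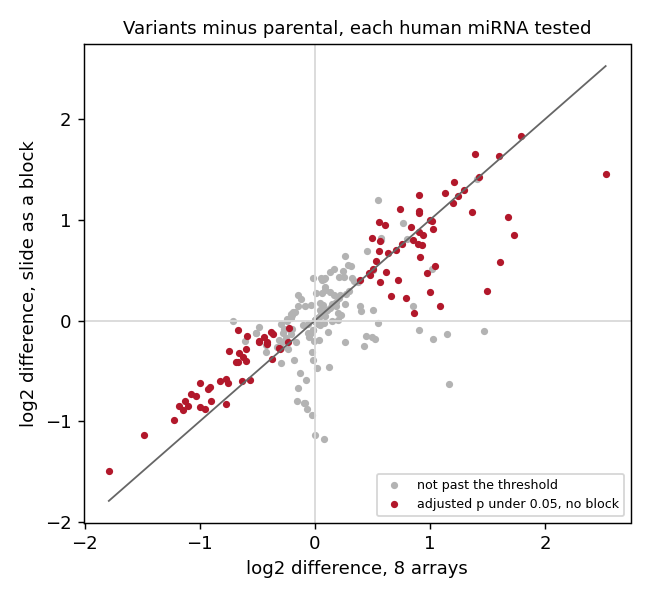
Log2 difference between variants and parental samples for each of 236 human miRNAs, over all 8 arrays (horizontal) and with the slide as a block (vertical), red where the adjusted p without the block is under 0.05. The 94 red points keep their sign on both axes, and 29 miRNAs pass the threshold with the block, 25 of them red. Parental replicate 1 enters both differences.

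Against the parental line, the round 1 variants MA1 and MC1 changed 66 miRNAs, 35 higher and 31 lower. miR-592 was at least 3.46-fold lower, miR-361-3p changed by -1.21 (SE 0.15), miR-221* by -1.38 (SE 0.28), miR-130a by -1.19 (SE 0.27) and miR-19b by -1.09 (SE 0.16). miR-874 rose by 1.91 (SE 0.46), miR-204 by 1.62 (SE 0.16), miR-218 by 1.41 (SE 0.29), miR-23a* by 1.30 (SE 0.35) and miR-193a-3p by 1.29 (SE 0.29). The difference of miR-23a* was 0.59 with the slide block (adjusted p = 0.28) and -0.055 with normexp, and that of miR-874 was 0.84 with the block (adjusted p = 0.075). Of these 10 miRNAs 4 passed with the block, miR-592, miR-361-3p, miR-19b and miR-204. miR-146a rose by 0.94 (SE 0.25; adjusted p = 0.038). With the slide as a block 26 miRNAs passed, 19 of them among the 66, and the miR-146a difference was 1.08 (limma, adjusted p = 0.14). Within the first slide limma called 0, with 32 at an unadjusted p under 0.05. Scaling over all probes gave 9 calls, 5 higher and 4 lower. Quantile normalization gave 23 higher and 31 lower, the median over common probes 22 and 34, the deposited log2 values 16 and 32, and normexp 10 and 20.

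The round 2 variants MA2 and MC2 changed 95 miRNAs against the parental line, 55 higher and 40 lower. miR-874 rose by 3.14 (SE 0.46), miR-371-5p by 2.23 (SE 0.31), miR-513b by 2.17 (SE 0.45) and miR-923 by 2.11 (SE 0.22), and miR-135a* was at least 4.47-fold higher. miR-874, miR-371-5p and miR-513b were measured on 1 of 4 parental arrays, and with the slide block miR-874 was 2.06 (adjusted p = 0.0052) and miR-513b 1.29 (adjusted p = 0.074). The block also ended the call of miR-221* (adjusted p = 0.066), and the other 8 passed. The value of miR-135a* was -0.045 with normexp. miR-592 was at least 3.46-fold lower, and miR-221* changed by -1.59 (SE 0.28), miR-7-1* by -1.48 (SE 0.14), miR-7 by -1.43 (SE 0.20) and miR-20a by -1.35 (SE 0.15). miR-146a rose by 1.32 (SE 0.25; adjusted p = 0.0088), and by 1.46 at an adjusted p of 0.043 with the slide as a block. With that block 75 miRNAs passed, and within the first slide 3. Of those 75, 62 were among the 95. The split was 19 higher and 28 lower with scaling over all probes, and 35 and 45 with quantile normalization. It was 39 and 52 with the median over common probes, and 33 and 52 with the deposited log2 values. With normexp it was 15 and 77, and the median of all tested miRNAs shifted by -0.37.

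Metastatic potential is described as rising with the rounds, and round 2 was compared directly with round 1, all on the first slide. The lines were not paired by name, since their descent from each other is not given. Here 4 miRNAs passed the test, 3 higher and 1 lower in round 2, and 10 passed with the MA or MC name as a block, 7 higher and 3 lower. Within the first slide limma called 0 (29 at an unadjusted p under 0.05), and also 0 with parental replicates 2 to 4 averaged (26). The fit over all 8 arrays takes its spread from the parental arrays too. miR-135a* rose by 1.47 (SE 0.22; adjusted p = 0.038) and miR-1225-5p by 1.03 (SE 0.10; adjusted p = 0.0064). miR-134, not well above background in round 1, was at least 2.00-fold higher in round 2 (adjusted p = 0.0064). miR-15b* changed by -0.60 (SE 0.09; adjusted p = 0.039). miR-146a differed by 0.38 (SE 0.29; adjusted p = 0.56). The miR-17-92 list had a median of -0.22 and a camera adjusted p of 0.05048, and 0.74 with an estimated correlation. At an unadjusted p under 0.05 there were 40 miRNAs.

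The variant lines carry the names MA and MC, with 1 line of each per round. MC lines were higher than MA lines in 7 miRNAs and lower in 11. This split was 12 and 23 with the median over common probes and 8 and 5 with quantile normalization. It was 6 and 4 with the deposited log2 values and 1 and 0 with scaling over all probes. miR-199a-5p was 1.59 log2 units higher (SE 0.17), miR-210, a hypoxia-responsive miRNA, 0.93 (SE 0.12), miR-455-3p 0.79 (SE 0.12), miR-10a 0.53 (SE 0.04) and miR-150* 0.47 (SE 0.05). miR-801 differed by -1.07 (SE 0.15), miR-338-3p by -0.88 (SE 0.15), miR-101 by -0.79 (SE 0.06), miR-873 by -0.76 (SE 0.08) and miR-876-5p by -0.68 (SE 0.04). These standard errors come from a fit over all 8 arrays, so they take in the parental spread. On the parental arrays miR-873 and miR-876-5p were not well above background. There miR-876-5p averaged 4.76 (SD 0.016), near the floor of 4.75, so its standard error says little about spread between lines. miR-146a differed by -0.57 (SE 0.19; adjusted p = 0.15). All MA and MC lines were on the first slide, so a slide block leaves these differences unchanged and only takes parental replicate 1 out of the spread. It gave 66 calls, as did leaving out that array, and is no check on the slide. With the 4 variant arrays alone limma called 0, with 48 at an unadjusted p under 0.05.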

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

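All tests of explanations in this part were chosen after the results were seen, except those of scaling, of array brightness and of other splits of the arrays. Among 90 groups of 4 values of called miRNAs, 20 held a lone array whose gap to its nearest neighbour, as a share of the range, exceeded Dixon's critical value, which chance does in about 1 in 20 groups. Parental replicate 1 was the lone array for miR-874, miR-513b and miR-876-5p (each 1, because the other 3 parental values were at the floor), miR-96 (0.956), miR-199b-5p (0.946), miR-10b (0.938), miR-494 (0.927), miR-19b (0.883), miR-15b (0.883), miR-221* (0.882), miR-16 (0.880), let-7i (0.878), miR-19a (0.852), miR-532-5p (0.847) and miR-7 (0.841). Among the variants MC1 stood apart for let-7i (0.950) and miR-204 (0.906), and MA2 for miR-494 (0.903), miR-503 (0.876) and miR-424 (0.833).

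Parental replicate 1, on the first slide, differed from the mean of parental replicates 2 to 4 by a median of 0.277 log2 units, while the median SD among those 3 was 0.042. The gap was 0.304 in the brightest tercile of miRNAs, with 0 of them at the floor on a parental array. Whether dim signal on the second slide adds to it stays open, because 57 of 79 miRNAs in the dimmest tercile were at the floor on at least 1 parental array, which limits their gap. Slide, scan and software version cannot be told apart from a difference between cultures, because the gap of 0.277 coincides with all of them.

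The 94 calls arose in 1 of 35 splits of the 8 arrays into 2 groups of 4, and the highest other split gave 5. This excludes chance only for arrays that are exchangeable, which the 3 similar arrays of the second slide are not. The 30 splits that part those 3 gave 0 calls in limma, and the 5 that keep them together, the real one included, are too few for a share under 0.05. With the slide as a block 29 miRNAs passed, 25 of them among the 94, and 9 passed with those 3 arrays averaged.

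The miR-17-92 members were lower in the variants. The list median minus that of all tested miRNAs was -0.648 in the scaling nearest to 0, and -0.449 with normexp background correction. A single factor per array moves the list and the other miRNAs nearly alike, so scalings of that kind could not test this. With quantile normalization, which is not a single factor, the value was -0.649. The list was not compared with miRNAs of like brightness. Parental replicate 1 minus replicates 2 to 4 was -0.274 in the brightest tercile and 0 in the dimmest, where the floor limits it. An effect that depends on brightness therefore stays open. The median was below -0.3 in 4 of 4 seed families, so the falls were not confined to 1 sequence family. This argues against cross-hybridization within 1 family as the cause of the whole list. The falls were already known when this test was chosen, and in the miR-92 family, with 3 members, miR-363 rose. Cross-hybridization between members of the same family, such as miR-18a and miR-18b, was not tested, so the falls of single members may not be separate. The median with the slide as a block was -0.596, but the block rests on 1 parental array, so slide and scan remain open, as does a difference of the variants themselves, which was not tested.

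Round 2 differed from round 1 in miR-135a* by 1.47, miR-1225-5p by 1.03, miR-134 by 1.00 and miR-15b* by -0.60. Over the 22 miRNAs higher in round 2 at an unadjusted p under 0.05, the median difference was 0.544 between MC2 and MC1, arrays of like brightness. This does not decide on brightness as the cause, because the miRNAs were chosen on the same arrays. Of 7 viral targets detected on at least 2 arrays, 4 exceeded the 90th percentile of human miRNAs in the same contrast, and the other 3 were lower in round 2, ebv-miR-BART12 by -1.89, ebv-miR-BART16 by -1.05 and ebv-miR-BART13 by -0.18. Signal from RNA other than mature human miRNA and a real difference between rounds both stay open.

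Probes for viral miRNAs entered none of the comparisons, and 3 of their targets were well above background in all 4 variants and higher than in parental samples. kshv-miR-K12-3 differed by 1.78 log2 units, hsv1-miR-LAT by 0.89 and ebv-miR-BART13 by 0.47. From the parental array of the same slide they differed by 1.62, 0.86 and 0.13. Whether signal from RNA other than mature human miRNA adds to the rises of human miRNAs in the variants was not tested. Of the targets detected on some variant arrays, ebv-miR-BART19-3p differed by 1.92, hcmv-miR-US33-5p by 1.23, hcmv-miR-US4 by 0.26, ebv-miR-BART16 by -0.40 and ebv-miR-BART12 by -0.71. In limma, MC lines differed from MA lines in miR-199a-5p by 1.59, miR-210 by 0.93, miR-455-3p by 0.79, miR-10a by 0.53 and miR-150* by 0.47. The lower ones were miR-801 by -1.07, miR-338-3p by -0.88, miR-101 by -0.79, miR-873 by -0.76 and miR-876-5p by -0.68. With the 4 variant arrays alone none of these 10 passed.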

How the results depend on the processing

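Normexp on median signals and averaging the second-slide parental arrays were chosen after the data were seen. So were the runs of the list tests under alternative settings, other than the estimated correlation. Normexp on mean signals was not run, because some files lack that column. Fitted over all spots it failed on MA1, where a few spots have a very bright local background, so it was fitted on spots without an outlier flag. Where no reason is given, the cause was not tested.

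For all variants against parental samples, 94 miRNAs became 52 without a filter, 57 with a floor 2 times higher, 29 with the slide as a block, 1 within the first slide (46 at an unadjusted p under 0.05) and 9 with the averaged parental arrays. Of the 29 with the block, 25 were among the 94. The other settings gave 67 to 113, and normexp 14 higher and 72 lower. Leaving out an array gave 59 (parental replicate 3) to 105. miR-146a was 0.65 with scaling over all probes, 1.27 with the block or within the first slide, and 1.18 with averaging, none of them past the threshold in limma, at adjusted p of 0.10, 0.07, 0.25 and 0.08. Leaving out an array gave 1.04 to 1.35. Over all settings its adjusted p ran from 6.61e-05 to 0.25.

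For round 1, 66 became 9 with scaling over all probes, 41 for miRNAs detected on all arrays (fewer tested), 10 without a filter, 26 with the block, 0 within the first slide (32 unadjusted), 30 with normexp and 0 with averaging (58). Leaving out an array gave 25 to 94: 36, 25 and 25 without parental replicates 2, 3 and 4, and 31 without MC1. For round 2, 95 became 47 with scaling over all probes, 53 without a filter, 3 within the first slide and 38 with averaging. Without MA2 there were 62, and without 1 of the other arrays up to 115.

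For round 2 against round 1, 4 became 14 with the software's total signal, 1 with scaling over all probes, 7 with the brightest probe, 1 for detection on at least 4 arrays and 2 on all, 1 with the deposited log2 values, 13 with the slide block, 0 within the first slide (29), 0 with averaging (26) and 10 with the MA or MC name as a replicate block. Leaving out an array gave 2 (parental replicate 3 or 4) to 13 (parental replicate 1), with 7, 12 and 11 without MA1, MA2 and MC2. Both rounds were on the first slide, so the slide block is the same fit as leaving out parental replicate 1.

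For MC against MA, 18 became 1 with scaling over all probes, 35 with the median over common probes, 11 for detection on at least 4 arrays and 5 on all, 6 without a filter, 9 with a floor 2 times lower, 10 with the deposited values, 66 with the block, 0 within the first slide (48), 0 with normexp (31), 0 with averaging (34) and 0 with the variant arrays alone (48). Leaving out an array gave 6 (parental replicate 3 or 4) to 66 (parental replicate 1), with 8 without parental replicate 2 and 38 without MA1 or MC1 and 30 without MA2 or MC2. For this comparison too, the slide block is the same fit as leaving out parental replicate 1.

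For the lists of variants against parental samples, 1 became 5 without a filter, 5 with normexp and 0 with an estimated correlation. For those of round 2 against round 1, 0 became 2 with the median over common probes, with mean log2 over probes or with a higher floor, 1 for detection on at least 4 arrays, with the block or within the first slide, and 6 without a filter. It ranged from 0 to 2 when 1 array was left out, with 1 without parental replicate 1, 3 or 4, MA1 or MA2, and 2 without MC2.

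Normexp adds an offset before scaling, which lifts dim miRNAs on the dimmer slide, and it turned the sign of miR-513b (-0.058), miR-135a* (-0.13, and -0.045 for round 2), miR-363 (-0.020), miR-503 (-0.21), miR-629 (-0.36), miR-873 (-0.26), miR-876-5p (-0.34), miR-532-5p (-0.14), miR-194 (-0.20) and, for round 1, miR-23a* (-0.055). miR-30b turned to 0.000469 with mean log2 over probes, miR-29c to -0.013 with scaling over all probes and miR-24 to 0.15 with quantile normalization. The named miRNAs past the threshold otherwise kept their direction, 1571 times past the threshold and 486 times not. Low signal over background on the second slide limits dim miRNAs.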

Other observations

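Between variants and parental samples, the further lists with at least 3 tested members had camera adjusted p of 0.36 to 0.67. In the miR-29 family 1 of 3 members rose, miR-29c, and in the miR-30 family 1 of 5 fell, miR-30b. In the family of miR-99, miR-100 and miR-125, miR-125a-5p fell, at -0.30 (SE 0.07), and in the miR-181 family miR-181b, at -0.38 (SE 0.07), with the other members not past the threshold. None of miR-29c, miR-30b, miR-125a-5p, miR-181b, miR-96, miR-513b, miR-494 and miR-194 passed in the fit with the slide block. Of the cluster of miR-183, miR-96 and miR-182, 1 of 2 tested members fell, miR-96, at -0.99 (SE 0.15) and at -0.62 with the slide as a block (adjusted p = 0.051), and neither miR-221 nor miR-222 passed, at -0.012 and -0.021. miR-222 was -0.93 with the slide as a block, where parental replicate 1 alone is the reference (limma, adjusted p = 0.012). In the X-chromosome cluster of miR-506 and miR-513 1 of 3 tested members rose, miR-513b, and 2 when adjusted over the list alone. In the chromosome 14 cluster 1 of 5 rose, miR-494, and 0 members of the placental chromosome 19 cluster were tested. Of 4 miRNAs of the p53 list 1 rose, miR-194, while miR-34a differed by 0.13 (SE 0.15). Among list members not past the threshold, the slide block turned miR-487b from 1.47 to -0.11, miR-30c from 0.52 to -0.18, miR-15a from -0.21 to 0.022 and miR-99b from 0.028 to -0.037. The other counts were the same when adjusted over the list alone. The blood marker miR-342-3p differed by 0.21 and the hypoxia-responsive miR-210 by 0.32, and neither passed.

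miR-923, a name with no miRNA gene in the RefSeq table, took 4.52% to 5.22% of the summed human signal on parental arrays, 12.3% on MA1, 9.38% on MC1, 25.8% on MA2 and 15.0% on MC2.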
